A study of Nothobranchius furzeri with 20 samples.

How the data were processed

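Polyadenylated-transcript libraries of muscle total RNA from male killifish were prepared with the TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 without stating their settings. The genome build, the annotation and the use of strand are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies could not be told apart from their counts.

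The authors deposited a table of raw counts per gene and a table of RPKM values, each with 26739 genes and 20 columns, 1 column per library. The count table held whole numbers that summed to between 24333849 and 38571967 per library. No row lacked a gene identifier, 4257 genes had a count of 0 in all libraries and 0 columns were left unused. Libraries of 1 group were compared by chi-square over genes with a summed count of at least 20. The lowest value was 29.6 per degree of freedom, far above the sampling noise of 1, so no library was counted as a duplicate.

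The deposited RPKM values were not scaled by the total of their own library. When the 20 library totals were assigned down the rows of the table in turn, running on from column to column, 100% of the nonzero RPKM values of the 3169 genes whose length the decimals fix were reproduced, and with each column's own total 5.10% were. Over 7616 genes with at least 1 RPKM in every library, the gene length implied by count and RPKM varied between libraries by a median of 0.000312 log2 units with the totals so assigned and by 0.91 with the own totals. Fold changes taken from these RPKM values carry an error that depends on the row, between -0.24 and 0.12 log2 units for the comparison of the 9-week groups, between -0.19 and 0.12 for 27 against 9 weeks with exercise and between -0.29 and -0.01 for 27 weeks against unexercised 9-week fish. The RPKM table was therefore used only as an alternative and as a source of gene lengths, which came out as whole numbers of bases within 0.05 for 100% of those 3169 genes and were recovered for 97.9% of tested genes.

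Gene identifiers were used as deposited. None of them, 0 of 26739, matched an entry of the 38438-gene reference table of assembly NfurGRZ-RIMD1. The 32 gene lists fixed before the data were examined (pathways, fibre types and markers of other cell types) therefore had no member that could be found, and neither the planned competitive and self-contained list tests nor the choice of genes by name was run. The naming rule, also fixed before the data were examined, took the genes with the largest absolute log2 fold change among those past the threshold, with a mean of at least 5 CPM in the higher group and groups that overlapped in at most 1 library, and asked for a gene symbol. With no symbol in reach, the first gene in each direction of the first 2 comparisons was taken by the rule without that condition. The rule so read was met by 17 higher and 9 lower genes for exercise at 9 weeks and by 705 higher and 1619 lower genes for age.

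Groups came from the labels: age and exercise. Libraries carry numbers only as names, given in the order of the sample codes, since the labels gave no replicate number, batch, litter or pairing. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed by filterByExpr with its minimum count of 10, which left 16653 genes. Counts were scaled by TMM factors, and a quasi-likelihood model with robust estimates was fitted to all 3 groups together with group as the only term; the common dispersion was 0.118. Each of the 3 comparisons was a two-sided contrast with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. Principal components, rank measures and correlations used log2 CPM with a prior count of 2. Measures with 1 value per library were compared by exact two-sided permutation tests, adjusted over a family of 15.

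The abundance measure of a library was the median deviation of the genes in the lowest of 5 abundance classes from their mean over all 20 libraries, minus that of the highest class. The concordance of comparisons was computed on differences of group means, with 20 simulated data sets without effect and 20 divisions of the shared group into 2 and 3 libraries. The test was checked on simulated counts with 200 changed genes per fold size. It recovered, of genes changed 1.5-, 2- and 4-fold, 0%, 41.3% and 82.1% for the 9-week groups, 0.508%, 48.7% and 89.0% for 27 against 9 weeks with exercise, and 0%, 55.0% and 91.4% for 27 weeks against unexercised 9-week fish. The adjusted threshold is stricter where few genes change. With only 200 changed genes, these rates do not carry over to the real 27-week comparisons, where 5276 and 6675 genes were called. False calls made up at most 4.35% of the calls in these simulations. Their counts were drawn for each gene independently from the fitted spread, without structure shared between libraries. The share of false calls in the real libraries is therefore not bounded by this value.

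Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no low-count filter, a mean of at least 1 CPM in a group as filter, DESeq2 1.42.0, limma-voom with sample weights (limma 3.58.1), a fit of the compared groups alone, the deposited RPKM values on a log2 scale with pseudocounts of 0.5 and 0.1 tested by limma-trend, the 50 most abundant genes left out, a threshold of 0.01, a test against a 1.5-fold change, a surrogate variable (sva 3.50.0) and each library left out in turn. Chosen after seeing the data were fits without 27-week libraries 1 to 5 or 6 to 10, RPKM recomputed with the own totals and tested by limma-trend with a pseudocount of 0.5, the 9-week groups alone and the abundance and top-gene measures with each library left out, and thinning of every library to the lowest total.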

Results

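Gene expression was measured by RNA sequencing of muscle from male turquoise killifish (Nothobranchius furzeri, a short-lived annual fish) of the strain MZM-04/10p. The series covered 20 libraries in 3 groups. From fish aged 9 weeks came 5 without physical exercise and 5 with exercise in a swim tunnel, a chamber in which a fish swims against a current. The other 10 came from fish aged 27 weeks with the same swim-tunnel label. The groups were formed by the label alone, so an equal amount of exercise at both ages cannot be assumed. Fish of 27 weeks without exercise were not analysed here, so age was compared within exercised fish only. Library totals ran from 24333849 to 38571967 gene counts. The number of detected genes was 20076 ± 346 (SD, n = 5) without exercise, 19795 ± 574 (SD, n = 5) with exercise at 9 weeks and 20036 ± 305 (SD, n = 10) with exercise at 27 weeks. The tables named genes by identifiers only, none of which was paired with a gene name, so only 4 identifiers are given below, each the first by a naming rule in its direction for exercise at 9 weeks or for age in exercised fish. The labels gave no animal identity, so p-values over libraries set group differences against the variation between these samples only. Sample codes ran in separate blocks for the 3 groups, so a batch that followed them could not be separated from exercise or age.

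Muscle libraries were dominated by few transcripts. The 50 most abundant genes of a library held 55.4% ± 3.02 (SD, n = 5) of its counts in unexercised fish, 58.5% ± 3.17 (SD, n = 5) in exercised fish of 9 weeks and 59.9% ± 2.38 (SD, n = 10) in exercised fish of 27 weeks. The share was 4.55 percentage points higher at 27 weeks than in unexercised fish of 9 weeks (two-sided exact permutation test over 3003 splits, p = 0.00566, adjusted p = 0.03 over the 15 tests of such library measures). The differences of 3.07 points with exercise at 9 weeks (exact permutation p = 0.159, adjusted p = 0.398) and of 1.48 points with age among exercised fish (exact permutation p = 0.33, adjusted p = 0.55) did not pass the test.

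The first principal component of the log2 CPM (counts scaled to equal library size) held 37.3% of the variance and the next 12.7%. All 10 libraries of 9-week fish lay between -56.4 and -18.1 on the first component. The 27-week libraries did not lie together on it. Libraries 1 to 5 of that group lay at 67.6, 78.7, 79.9, 77.9 and 81.8, and libraries 6 to 10 at -13.5, 9.5, 5.6, 5.2 and 19.2; the labels of all 10 were alike in age, sex, strain, tissue and exercise. The gap between 19.2 and 67.6 made up 0.507 of the range of the group. The median gene had an SD of 0.43 in log2 CPM between the 27-week libraries, against 0.27 between unexercised and 0.32 between exercised libraries of 9 weeks.

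**Figure D1:**
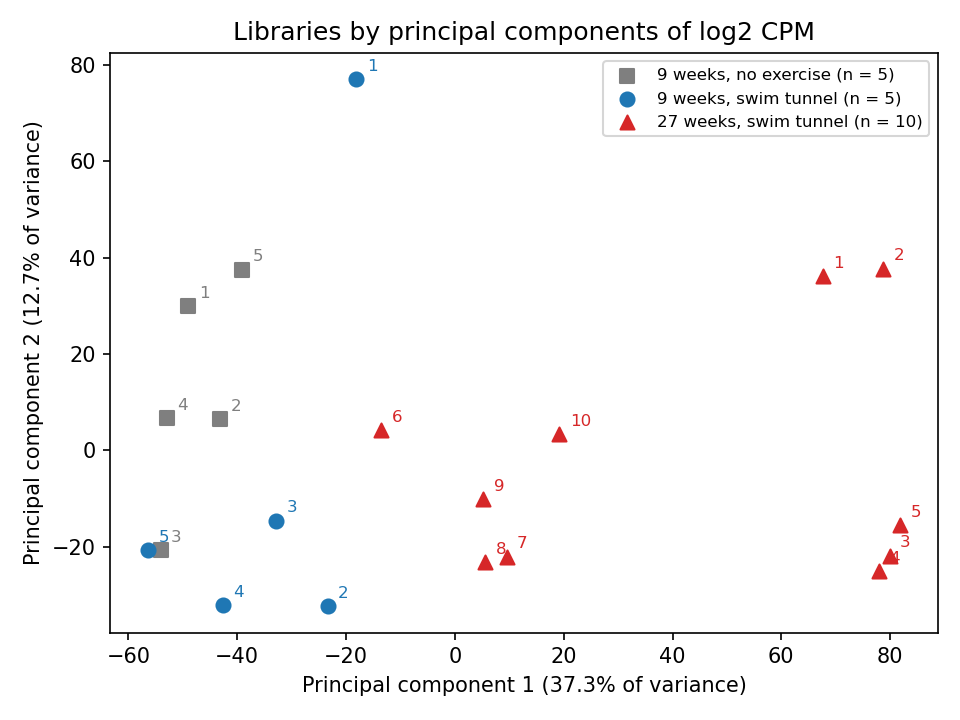
Each point is a library, placed by its first principal component (horizontal axis) and its second (vertical axis) of log2 CPM over 16653 genes, with colour and shape for the group and a number naming the library. The 9-week libraries lie between -56.4 and -18.1 on the horizontal axis, 27-week libraries 1 to 5 between 67.6 and 81.8, and 27-week libraries 6 to 10 between -13.5 and 19.2.

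The comparison of the 9-week groups addressed the effect of exercise in young fish. After exercise 18 genes were higher and 12 were lower, of 16653 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The balance of directions turned to 45 higher and 47 lower with a surrogate variable. With RPKM on own totals, tested by limma-trend, it turned to 9 higher and 16 lower. The gene with the largest increase among the called genes, Nfu_g_1_003551 (1869 bases), stood at 80.9 ± 59.6 CPM (SD, n = 5) with exercise and at 7.14 ± 2.80 CPM (SD, n = 5) without, a log2 fold change of 3.50 (SE 0.57, edgeR adjusted p = 0.012). It was between 19.0 and 157.7 CPM in the exercised libraries and between 3.65 and 10.2 CPM in the unexercised ones. The largest decrease among the genes that met the naming rule was that of Nfu_g_1_018732 (1231 bases), from 11 ± 2.28 CPM (SD, n = 5) to 2.59 ± 0.83 CPM (SD, n = 5), a log2 fold change of -2.09 (SE 0.34, edgeR adjusted p = 0.012). Its highest exercised library, at 3.53 CPM, lay below its lowest unexercised library, at 8.36 CPM.

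Few of the called genes changed at least 4-fold, 1 of them higher and 2 lower. The median log2 fold change was 1.05 over the 18 higher genes and -1.18 over the 12 lower genes, and 10 of the former and 9 of the latter changed at least 2-fold. The higher genes together held 0.0732% ± 0.0163 (SD, n = 5) of all counts with exercise and 0.0336% ± 0.00444 (SD, n = 5) without. The lower genes held 0.00842% ± 0.00284 (SD, n = 5) with exercise and 0.0269% ± 0.00653 (SD, n = 5) without. The exercised and unexercised libraries did not overlap in CPM for 855 genes, 503 of them higher and 352 lower with exercise. Chance gives 0.794% of genes on average, or 132.2 genes, though single splits that mixed the labels reached up to 781. Of the called genes, 27 were among the 855. At an unadjusted p under 0.05 the test found 2269 genes, where 832.65 are met by chance on average.

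The number of called genes rested on which libraries entered the fit. It was 12, 1, 13 and 12 without unexercised libraries 2, 3, 4 and 5 in turn, 12, 12, 7 and 92 without exercised libraries 1 to 4 in turn, 174 with the 9-week groups fitted alone (6 without unexercised library 2 or 3 in that fit and 605 without exercised library 4), 348 with DESeq2 and 585 with limma-voom. Without unexercised library 3 the calls of Nfu_g_1_003551 (edgeR adjusted p = 0.0558) and Nfu_g_1_018732 (adjusted p = 0.0542) ended, and that of Nfu_g_1_018732 also ended without exercised library 3 (adjusted p = 0.0517). Counts were also simulated with the depth of these libraries and a spread estimated jointly over all 3 groups, not over the 9-week groups alone. In them the test recovered 82.1% of genes changed 4-fold, 41.3% of those changed 2-fold and 0% of those changed 1.5-fold.

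Age was compared within exercised fish, 27 weeks against 9 weeks. Of the 16653 genes, 2471 were higher and 2805 were lower at 27 weeks (edgeR quasi-likelihood test, adjusted p under 0.05). Among those that met the naming rule, Nfu_g_1_001848 (4090 bases) rose most, from 11.4 ± 5.36 CPM (SD, n = 5) to 206.7 ± 102.9 CPM (SD, n = 10), a log2 fold change of 4.18 (SE 0.50, edgeR adjusted p = 1.34e-05). Every 27-week library, at 65.9 CPM or more, lay above every exercised 9-week library, at 18.7 CPM or less. The unexercised 9-week fish had 40.8 ± 29.2 CPM (SD, n = 5) of this gene, with library 5 at 92.9 CPM and the other 4 libraries between 25.3 and 29.9 CPM. Its log2 fold change with exercise at 9 weeks was -1.84 and did not pass the test (SE 0.48, edgeR adjusted p = 0.106).

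The largest decrease with age among the genes that met the naming rule was that of Nfu_g_1_001750 (732 bases), from 37.36 ± 15.04 CPM (SD, n = 5) to 3.11 ± 4.56 CPM (SD, n = 10), a log2 fold change of -3.60 (SE 0.79, edgeR adjusted p = 0.00195). This gene was nearly absent from 27-week libraries 1 to 5, with 3 to 7 counts each, and stood at 14.0, 3.00, 3.44, 7.86 and 2.05 CPM in libraries 6 to 10. The lowest 9-week library, exercised or not, had 18.9 CPM. Exercise at 9 weeks made no detectable difference to it (log2 fold change 0.29, SE 0.91, edgeR adjusted p = 0.939). The fold change with age was -4.34 without library 6, -2.62 without libraries 1 to 5 and -7.96 without libraries 6 to 10, each still past the threshold.

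**Figure D2:**
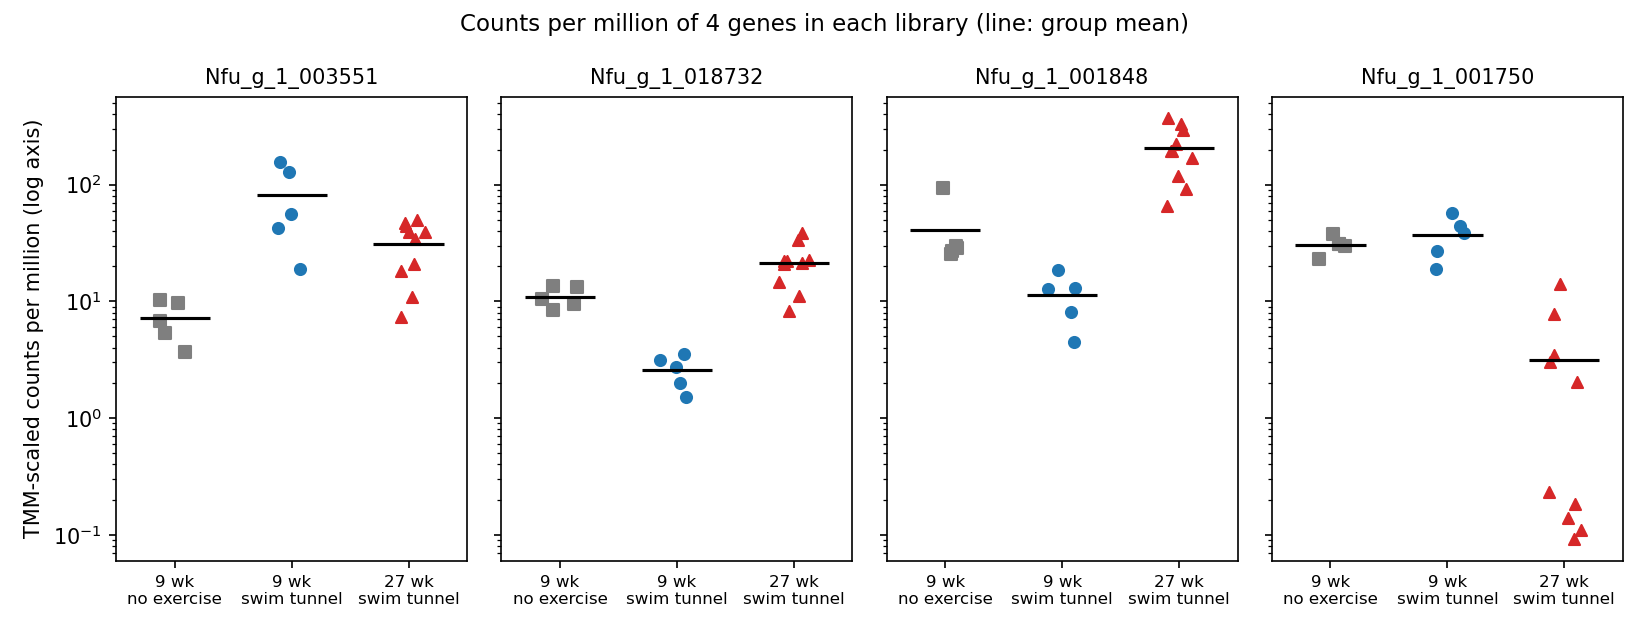
Each panel gives 1 gene, with the CPM of every library on a logarithmic vertical axis, the 3 groups along the horizontal axis and a line at each group mean. Nfu_g_1_003551 is higher and Nfu_g_1_018732 lower in all 5 exercised than in all 5 unexercised libraries of 9 weeks, while at 27 weeks Nfu_g_1_001848 lies at 65.9 CPM or more and Nfu_g_1_001750 at 14.0 CPM or less.

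Both genes that led the exercise comparison also changed with age among exercised fish, each towards the level of unexercised fish or past it. Nfu_g_1_003551 was lower at 27 than at 9 weeks, at 31.1 ± 15.5 CPM (SD, n = 10), with a log2 fold change of -1.38 (SE 0.43, edgeR adjusted p = 0.0198). Nfu_g_1_018732 was higher, at 21.5 ± 9.29 CPM (SD, n = 10), with a log2 fold change of 3.06 (SE 0.33, edgeR adjusted p = 5.57e-06). Both comparisons drew on the same exercised 9-week libraries, which alone can produce opposite signs.

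The genes called between the ages were many and reached into the abundant transcripts. The median log2 fold change was 0.93 over the higher and -0.76 over the lower genes, with 1071 and 780 of them changed at least 2-fold and 163 and 63 at least 4-fold. Genes higher at 27 weeks held 14.2% ± 2.05 (SD, n = 10) of all counts there and 6.59% ± 1.12 (SD, n = 5) in exercised fish of 9 weeks, whereas the lower genes held 14.1% ± 1.34 (SD, n = 10) and 22.5% ± 2.08 (SD, n = 5). The 27-week and 9-week libraries did not overlap for 1467 genes, 430 higher and 1037 lower, all of them called. Chance gives 0.0666% of genes on average, or 11.1, though single splits can go above this.

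The direction of the age difference depended on abundance. In 5 equal classes of genes by mean abundance, from lowest to highest, the median log2 fold change with age among exercised fish was 0.20, 0.14, 0.06, -0.03 and -0.15. Of the genes called lower, 1027 were in the highest class, against 409 called higher there, while the class next to the lowest had 591 higher and 310 lower genes. Taken per library as the median deviation of the lowest class minus that of the highest, the measure was 0.23 ± 0.24 in log2 units (SD, n = 10) at 27 weeks, -0.25 ± 0.32 (SD, n = 5) in exercised and -0.20 ± 0.22 (SD, n = 5) in unexercised fish of 9 weeks. The difference in means of 0.48 from exercised fish of 9 weeks passed the test (exact permutation p = 0.00599, adjusted p = 0.03, 3003 splits), as did that of 0.43 from unexercised fish (exact permutation p = 0.004, adjusted p = 0.03). Single libraries overlapped, with 27-week values from -0.05 to 0.77 and exercised 9-week values from -0.50 to 0.32. Between the 9-week groups the difference was -0.05 (exact permutation p = 0.778, adjusted p = 0.83). Without 27-week libraries 1 to 5 the difference from exercised fish was 0.30 and no longer passed (exact permutation p = 0.0714), and that from unexercised fish was 0.25 (exact permutation p = 0.0476, not adjusted).

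**Figure D3:**
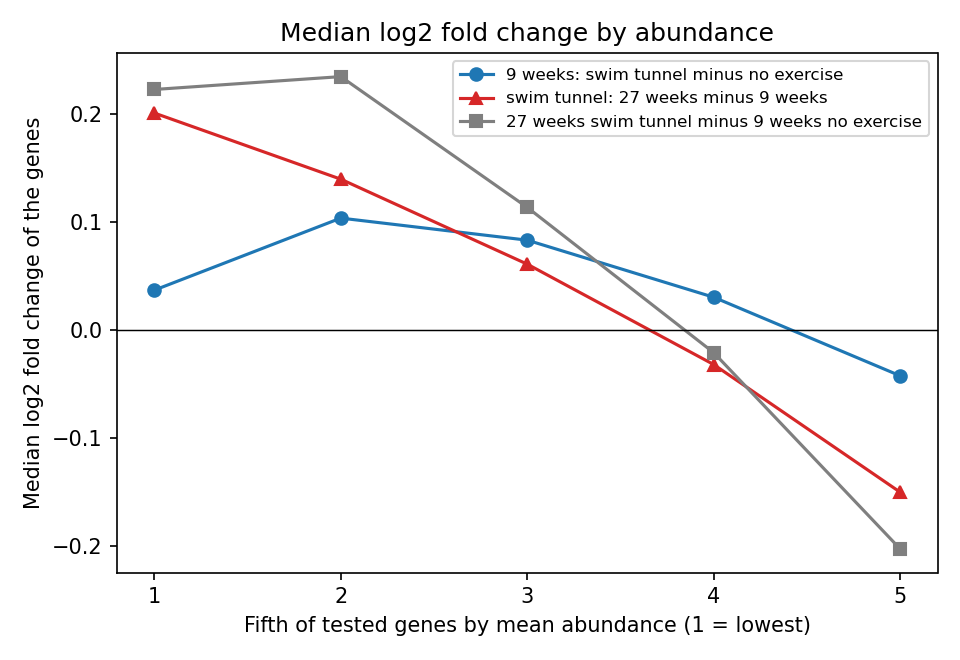
The median log2 fold change (vertical axis) is plotted for 5 classes of tested genes ordered by mean abundance (horizontal axis, 1 for the lowest), with a line for each comparison of groups. Both comparisons with 27-week fish fall from 0.20 and 0.22 in the lowest class to -0.15 and -0.20 in the highest, and the comparison of the 9-week groups runs between 0.10 and -0.04.

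Across genes, which are not independent replicates, the Spearman correlation of the log2 fold change with gene length was -0.00943. The median length was 2745 bases for higher, 2677.5 bases for lower and 2817 bases for uncalled genes. The number of called genes was 8320 without 27-week libraries 6 to 10 and 3765 without libraries 1 to 5, and 2575 of the 5276 genes, 886 higher and 1689 lower, were called in the same direction in both of these fits, which used the same 9-week libraries. With upper-quartile scaling 3201 genes were higher and 2338 lower, which turned the balance of directions from 46.8% to 57.8% higher; it also turned without a low-count filter (51.4%) and without 27-week library 8 (52.5%).

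Fish of 27 weeks with exercise were also set against fish of 9 weeks without it, a comparison in which age and exercise differ together and cannot be separated. Here 3529 genes were higher and 3146 lower at 27 weeks (edgeR quasi-likelihood test, adjusted p under 0.05), 1568 and 985 of them by at least 2-fold. All 4 named genes passed. Nfu_g_1_003551 was higher at 27 weeks (log2 fold change 2.12, SE 0.50, edgeR adjusted p = 0.00267), as were Nfu_g_1_018732 (0.97, SE 0.29, adjusted p = 0.0119) and Nfu_g_1_001848 (2.34, SE 0.45, adjusted p = 0.000496), whereas Nfu_g_1_001750 was lower (-3.31, SE 0.78, adjusted p = 0.00261). The higher genes held 20.2% ± 2.65 (SD, n = 10) of counts at 27 weeks and 9.51% ± 0.727 (SD, n = 5) in unexercised fish, and the lower genes held 13.3% ± 1.48 (SD, n = 10) and 24.5% ± 2.503 (SD, n = 5). The number of called genes was 4248 without 27-week libraries 1 to 5. The balance of directions, 52.9% higher, turned to 45.4% without these libraries, 48.3% without libraries 6 to 10, 48.1% at a threshold of 0.01, 49.9% without the 50 most abundant genes, 42.7% with RPKM on own totals and 26.0% and 26.9% with the deposited RPKM, the RPKM values all tested by limma-trend.

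The lists from the 3 comparisons overlapped. Of the genes higher at 27 weeks than in exercised fish of 9 weeks, 1881 were also higher than in unexercised fish, and of the lower genes 2141 were also lower, where independent lists would share 523.6 and 529.9; these comparisons share the 27-week libraries, and 2 genes were higher in the former and lower in the latter comparison, 3 the reverse. Of the 18 genes higher after exercise at 9 weeks, 8 were also higher at 27 weeks than in unexercised young fish (3.81 for independent lists), 12 were lower at 27 weeks than in exercised young fish (3.03) and 3 were higher than in these (2.67). Of the 12 genes lower after exercise, 9 were lower at 27 weeks than in unexercised young fish (2.27), 5 were higher than in exercised young fish (1.78) and 0 were lower than in these (2.02). Each of these pairs of comparisons shared 5 libraries, and part of the overlap may come from them.

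Across all 16653 genes, which are not independent replicates, the fold changes with exercise at 9 weeks and with age from exercised 9-week fish had a Pearson correlation of -0.144 and a covariance of -0.0407, where simulated groups without any effect gave -0.576 and -0.0641. The correlation was 0.0613 on average, between -0.154 and 0.244, when the shared libraries were divided so that each comparison had its own. With the difference between exercised 27-week and unexercised 9-week fish the exercise fold changes had a correlation of 0.449 and a covariance of 0.14, against 0.574 and 0.0638 in simulated groups; with divided libraries the correlation was 0.285 on average, between 0.139 and 0.433. The covariance exceeded the simulated value by 0.0233 in the former and by 0.0765 in the latter case. The simulated spread was estimated over all 3 groups together, and the size of these excesses depends on it. With divided libraries the covariance ran from -0.0428 to 0.104 in the former case, so its sign was not settled, and from 0.0574 to 0.137 in the latter.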

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

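Of the tests below, the fit of the 9-week groups alone was planned and the thinning tests had their outcome bounds set before they were run; the tests on transcripts of another tissue, gene length, exchanged libraries and other splits were chosen after the results had been seen.

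In groups of 5 or 10 libraries, 13 per-library measures gave 39 groups, in 3 of which a library stood far from the rest by Dixon's ratio of gap to range, where chance gives about 1 in 20 groups, or 1.95. Library 1 of the exercised 9-week fish had 77 on the second principal component, with the other 4 between -32.4 and -14.6. The same library had 0.32 in the abundance measure, against -0.50 to -0.30 in the other 4. Library 5 of the unexercised fish had 92.9 CPM of Nfu_g_1_001848, against 25.3 to 29.9 CPM in the other 4.

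The 27-week libraries stood apart from each other on the first principal component, with a gap of 0.507 of their range between libraries 1 to 5 and libraries 6 to 10. Depth was argued against, since the gap was still 0.51 or more of the range in 10 thinnings of every library to the lowest total. Between 3.29% and 4.30% of the 5377 genes with at least 10 CPM were at least 4-fold lower in libraries 1 to 5 than in exercised 9-week fish (0.80% or less in the other libraries). RNA added from a tissue without these transcripts could bring this about only as 75% or more of a library. The 50 most abundant 9-week genes held 56.4% or more of counts there, so such an added tissue would have to hold these in bulk too. The bound does not cover a minor tissue present in the other libraries and missing from libraries 1 to 5, which was not tested. Without gene names neither case can be told apart from a change within muscle. Loss of RNA by transcript length was argued against, since the deviations of libraries 1 to 5 had a Spearman correlation with gene length of at most 0.021 in size across genes, below the 0.086 reached among 9-week libraries. The sample codes of libraries 1 to 5 all come before those of libraries 6 to 10, so a difference between batches, in handling, between fish or between labels and fish that the labels do not record stays open, and no biological explanation was tested, since the labels of the 10 libraries were alike. The codes of the 3 groups do not mix either, so the same holds for the comparisons of exercise and of age.

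Few genes were called between the 9-week groups, and their number moved with the libraries in the fit. A spread estimated jointly with the varied 27-week group may hold the number down: the 9-week groups alone gave 174 genes, with 26 of the 30 among them, and the fits without 27-week libraries 1 to 5 or 6 to 10 gave 328 and 522, each with all 30; the number from the 9-week groups alone moved with single libraries, from 6 genes without unexercised library 2 or 3 to 605 without exercised library 4. Of 100 splits of the 9-week libraries, 2 gave 30 genes or more. They were the real one and the split that exchanged exercised library 1 with unexercised library 3, which gave 248, several times the real number. Of the 99 splits other than the real one, 95 gave no called gene. Chance alone cannot be excluded, since a split that mixed the labels exceeded the real one and not every possible split was run. The exchange may reflect a structure of the samples. An exchange of these libraries cannot be told apart from variation between fish: exercised library 1 lay at -0.37 between the means of the remaining libraries (0.5 for exercised, -0.5 for unexercised), on the side of the unexercised fish, as did exercised library 4 at -0.057, but unexercised library 3 lay at -0.088, still on its own side by less than the SD of 0.129 of its group, and the real split left more genes without overlap (855) than the exchanged one (611) or any other split of these libraries, the next being the exchange of exercised library 4 with unexercised library 1 (781 genes apart, 2 called). Exercise itself stays among the open explanations for the called genes.

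At 27 weeks the median gene of the low abundance classes was higher and that of the highest classes lower than at 9 weeks, with genes called in both directions in each class. Depth was argued against as the cause of the difference of 0.482 log2 units between the lowest and highest abundance classes, since it was 0.469 or more in each of 10 thinnings, with an exact permutation p of 0.00666 or less. Age, the composition of the muscle and RNA quality stay open as untested explanations, and the difference did not pass without 27-week libraries 1 to 5 (0.30, exact permutation p = 0.0714).

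For the age comparison 1 of 100 splits, the real one, gave as many genes as 5276, the highest other giving 1738. For 27-week against unexercised 9-week fish 1 of 100 gave as many as 6675, the highest other giving 1632. With 100 of 3003 splits run for each, this argues against a random division of the libraries as the source of these numbers. It does not bear on a batch or handling that differed between the groups. The splits with 1738 and 1632 genes put 27-week libraries 6 to 10 on one side and most of libraries 1 to 5 on the other, which again points to the structure of the 27-week group.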

How the results depend on the processing

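Each named gene was rerun only in the comparison that named it, and there its direction held under each alternative run. Nfu_g_1_003551 lost its call in 5 of 26 alternatives and Nfu_g_1_018732 in 4 of 26 (adjusted p up to 0.168 and 0.262), whereas Nfu_g_1_001848 and Nfu_g_1_001750 kept theirs in all 31.

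The number of genes called between the 9-week groups, 30, was 28 to 35 with RLE and upper-quartile scaling, the CPM filter and the 50 most abundant genes left out. It was 16 without a low-count filter, 92 with a surrogate variable, 174 in a fit of these groups alone, 348 with DESeq2 and 585 with limma-voom. It was 0 at a threshold of 0.01 and 0 against a 1.5-fold change in edgeR, where 2269 genes had an unadjusted p under 0.05. Leaving out single libraries gave 1 (unexercised library 3) to 92 (exercised library 4). The deposited RPKM, tested by limma-trend, gave 20 genes, 0 higher and 20 lower, and 18 with the smaller pseudocount, against 25 with own totals (9 higher). Chosen after seeing the data, the fits without 27-week libraries 1 to 5 and 6 to 10 gave 328 and 522, and the 9-week groups alone gave 6 (without unexercised library 2 or 3) to 605 (without exercised library 4) in place of 174.

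For age among exercised fish, the number fell from 5276 to 2924 at a threshold of 0.01 and to 904 against a 1.5-fold change; it was 8320 without 27-week libraries 6 to 10. For 27-week against unexercised fish it fell from 6675 to 4099 and 1620, and to 4248 without libraries 1 to 5. The stricter thresholds lower counts by construction. The other causes were not tested, except the shared spread weighed above. All 15 single libraries left out kept these counts within 1.5-fold (3970 to 5926 and 5542 to 7147). The share of higher genes was 46.8% and 52.9%, 57.8% and 60.0% with upper-quartile scaling, which moved the median of all genes to 0.12 and 0.14 log2 units from 0.03 and 0.06, and 32.5% and 26.0% with the deposited RPKM.

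The correlation of the exercise and age fold changes, -0.144, was -0.0724 over genes above 10 CPM and turned to 0.0613 with the shared libraries divided, which removes their common error; that with the difference from unexercised fish, 0.449, moved to 0.285. The abundance difference kept its sign and its p under 0.05 without any single library.

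No list test or its alternatives (estimated correlation, fry, RLE scaling, exact symbols, libraries left out) was run, since no gene name was in reach. Of genes changed 1.5-fold in simulated counts, 0.508% or fewer were recovered in each comparison.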
